A study of Mus musculus with 4 samples.

How the data were processed

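Gene expression was measured in splenic monocytes of mice that lack the microRNA miR-146a (KO) and of control mice (WT). Per the labels' protocols, CD11b-positive spleen cells were enriched with magnetic beads, stained for Ly6C and sorted by flow cytometry into a Ly6Chigh and a Ly6Clow fraction, and RNA from several mice was pooled for each array. The 4 groups (WT Ly6Chigh, WT Ly6Clow, KO Ly6Chigh and KO Ly6Clow) had 1 array each. The labels' protocols name a pair of red cell lysis buffers and can be read as a different one for each genotype. On that reading, which is not certain, buffer and genotype cannot be told apart in any comparison of KO with WT. The strain labels also differ: C57BL/6 for WT and B6(FVB)-Mir146tm1.1Bal/J for KO, although the source labels call the controls littermates.

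RNA was hybridized to Affymetrix GeneChip Mouse 430_2 arrays. Raw data were made with Expression Console 1.2.1 per the labels' design text, and GCOS is named in the submitters' processing notes without a version. The deposited signal intensities are linear, and their mean without the lowest and highest 2% was 150.0 on each array, so the authors had scaled each array to a common level. The algorithm behind the signals is not given in the sources used here. The deposited table also gave a detection p-value and a detection call (Present, Marginal or Absent) for each probe set and array. For 6 comparisons of 1 array with another, the authors' deposited table gave a signed fold change, a change call, a score and plot coordinates. Of these, the change calls were set beside the calls made here, and the authors' deposited scores were not used. A further deposited value table was the same as the signal columns in all 180404 values (0 differed).

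Of 45101 probe sets, 34958 were annotated to 1 gene symbol, 932 to several and 9211 to none, and no gene was named from a probe set with several symbols. Symbols were updated through the gene identifiers of a RefSeq gene table of assembly GRCm38.p6, which was used for names and gene order only. Each of the 18194 genes was represented by the probe set with the highest mean signal over the 4 arrays. Of these genes, 11099 were Present on at least 1 array and 8590 on all 4. The probe set for Ly6c1 and Ly6c2 carries both symbols, and these genes were not analysed here. The targeted gene Mir146 was likewise not analysed here, so the genotype labels were not checked at the target. The planned comparison of genes with and without miR-146a seed matches in their 3 prime untranslated regions was not run, since it needs sequence that was not used here.

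With 1 array per group there is no replicate, and pairwise comparisons have no p-value and no standard error. Log2 ratios were formed from the deposited signals without an offset. A gene was called higher or lower when the log2 ratio was at least 1 in size (2-fold), the probe set was Present on the brighter array and its signal there was at least 100. Where the dimmer array did not call the probe set Present, the fold is given as at least the brighter signal over the larger of the dimmer signal and the 95th percentile of Absent signals on that array, a bound chosen after the data were seen. A dimmer signal called Present was used as it was, even under that percentile, so a bound and a measured fold of a dim gene cannot be compared. The number of arrays limits the precision.

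For each gene list, the median log2 ratio of its measured members (Present on at least 1 array of the comparison) was placed among the medians of 10000 random lists of the same size, matched on mean signal in 20 bins. A median outside the central 95% of random lists is called above or below. This describes these arrays and is no test, and about 5% of lists lie outside by chance. The 26 lists, fixed before the data were examined, covered miR-146a targets from the literature, NF-kB and type I interferon response genes, MHC class II presentation, Toll-like receptors, osteoclast differentiation, Fc and complement receptors, chemokine receptors, cell cycle, immediate early and heat shock genes, sterol and lipid handling, markers of the Ly6Chigh and Ly6Clow subsets, sex-linked genes, and markers of neutrophils and their precursors, NK, B, plasma and T cells, conventional and plasmacytoid dendritic cells, red pulp macrophages, eosinophils with basophils and mast cells, platelets, and erythroid cells. Lists with fewer than 3 measured members got no median.

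The genes named were fixed by rule before the data were examined: up to 12 called genes each way per comparison with a signal of at least 500 on the brighter array, leaving out those with another Present probe set that changed 2-fold the opposite way, up to 4 called members per list, Traf6, Irak1, Relb and Itgam whatever their change, and the 6 largest differences each way between the KO effects at that signal. Genes named outside this rule are said to be so.

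An additive model of genotype and subset was fitted to the 4 arrays with limma 3.58.1 in R 4.3.3 on log2 signals of genes Present on at least 1 array, with Benjamini-Hochberg adjustment and a threshold of 0.05. It leaves 1 residual degree of freedom, the genotype by subset interaction, so any real interaction is taken for noise. Other steps used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

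The steps were tested on simulated data. For the 2-fold rule the noise was normal, with the spread of the additive model's residuals in each of 20 bins of signal. Both simulated arrays took the WT detection calls. For KO against WT in Ly6Chigh, the 2-fold rule on 18194 genes found 99 of 100 genes changed by 2 on the log2 scale and 0 of 100 changed by 0.5, and for Ly6Clow 100 of 100 and 0 of 100. For the limma fit on 11099 genes with variances drawn from its own prior, it recovered 0 of 50 genotype changes of 1 and 0 of 50 of 2 on the log2 scale, 40 of 50 of 4 and 48 of 50 of 6. With variances equal among genes of the same signal level, it recovered 0 of 50 changes of 1 and 2 of 50 of 2. On these same arrays, which meet its own assumption, a fit with an empirical Bayes trend recovered 32 of 50 and 44 of 50. With variances drawn from the prior, the trend fit recovered 0 of 50 and 2 of 50. For list medians in Ly6Chigh, 13 of 200 unshifted random lists lay outside the central 95%, and 93 of 100 lists shifted by 0.3 lay above it.

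The alternatives tried were quantile normalization, centring on the median, an offset of 32 before the log, other detection filters, signal minimums and fold thresholds, the mean of all probe sets of a gene, unmatched random lists, the authors' change calls, an empirical Bayes trend in limma and a window of 25 in place of 50 genes on each side of Mir146. The mean of all probe sets included those not Present, with signal and detection taken from the brightest one.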

Results

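Transcripts of splenic Ly6Chigh and Ly6Clow monocytes were measured on 4 arrays, 1 each for WT Ly6Chigh, WT Ly6Clow, KO Ly6Chigh and KO Ly6Clow, each made from pooled RNA of several mice. Ly6Chigh monocytes are the classical, inflammatory subset and Ly6Clow monocytes the subset that patrols vessels. miR-146a is a microRNA that represses Traf6 and Irak1, signalling proteins downstream of Toll-like and interleukin 1 receptors, and the study asked which genes it targets in each subset. With 1 array per group, no difference given here has a replicate check, an error or a p-value, except in the additive model. Between 46.8% and 48.6% of the probe sets were called Present. The 3 prime to 5 prime signal ratio was 1.20 (WT Ly6Chigh), 1.42 (WT Ly6Clow), 1.28 (KO Ly6Chigh) and 1.23 (KO Ly6Clow) for actin, and 0.894, 1.12, 0.905 and 0.950 for Gapdh in the same order. Mir146 itself was not analysed here, so the genotype labels were not checked at the targeted gene.

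In Ly6Chigh monocytes, the stress-inducible chaperone genes Hspa1b and Hspa1a rose 3.32-fold and 3.27-fold in KO over WT, to signals of 996.8 and 622.3 from 300.4 and 190.6. They are near-identical copies whose probe sets can share signal. The inflammatory cytokine gene Il1b rose 2.68-fold (signal 2425.7 against 906.1), the chemokine receptor gene Ccr1 2.41-fold, Thbs1, which encodes the matrix protein thrombospondin 1, 2.29-fold, and Ccl2, the ligand of the monocyte receptor Ccr2, 2.14-fold. Clec2d, a C-type lectin and ligand of an NK cell receptor, fell by 1.75 on the log2 scale (signal 296.3 against 993.9). Pttg1, the gene of securin, which keeps sister chromatids from separating before anaphase, fell by 1.26. S100a8, a calcium-binding protein abundant in neutrophils and monocytes, fell by 1.19 and Lpl, the lipoprotein lipase gene, by 1.02.

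Of 10402 genes measured in Ly6Chigh, 28 passed the 2-fold rule, 17 higher and 11 lower in KO (14 and 15 with median centring). The remaining large changes among bright genes were Crybg1 (log2 1.35), Gcnt2 (1.03) and Gm6377 (1.02). Other Present probe sets of Gcnt2 ranged from -0.31 to 1.33, and the other probe sets of Pttg1 gave -0.61 and -0.29. Values fell under the rule for Pttg1 with the mean of its probe sets (-0.72), for Gcnt2 and Gm6377 with median centring (0.98 and 0.97) or an offset of 32 (0.99 and 0.95) and for Lpl with quantile normalization (-0.98) or the mean of its probe sets (-0.85). Lcn2, a neutrophil granule protein gene, fell by 1.23. Itgam, which encodes the CD11b used for bead selection, was at log2 0.24.

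None of 15 measured miR-146a targets from the literature passed the rule in Ly6Chigh (0 of 15). The rule called 28 of all 10402 genes and found 0 of 100 simulated changes of 0.5 on the log2 scale. The count therefore cannot tell whether the targets changed by less than 2-fold. Traf6 was at log2 0.05, Irak1 at -0.08 and Relb, an NF-kB subunit, at 0.02, and the median of the list was 0.02, at percentile 73.7 of matched random lists. The median of NF-kB response genes was 0.20 (percentile 99.97), with Il1b the called member of 24. Type I interferon response genes had a median of 0.18, above all random lists, with 0 of 23 called and 20 above 0. Immediate early and heat shock genes had a median of 0.20 (99.98), with Hspa1a and Hspa1b the 2 called of 15. This group holds genes that respond to cell stress and handling, and its median lay on the same side as those of the NF-kB and interferon groups. Its members were not uniform, with 9 of 15 above 0. In the additive model, which averages the subsets, Fos was at -0.05, Dusp1 at -0.08, Ier2 at 0.04, Nr4a1 at -0.11 and Egr1 at -0.51. Fosb was at 0.84, Hsph1 at 0.70, Jun at 0.64 and Atf3 at 0.62. The labels can be read as a different lysis buffer for each genotype.

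MHC class II presentation genes had a median of 0.19 (percentile 97.8) and Toll-like receptors and adaptors one of 0.14 (98.8), with 0 of 9 and 0 of 19 called. The percentiles were 93.4 and 95.7 against random lists not matched on signal, and the Toll-like receptor median was 0.05 (85.9) with the mean of all probe sets. Markers of the Ly6Clow subset lay below random lists at a median of -0.38, with 0 of 17 called, but at -0.12 (percentile 12.5) with the mean of all probe sets of a gene. Neutrophil markers had a median of -0.52 (percentile 0.01) with S100a8 called among 8, but -0.11 (24.2) among members Present on both arrays. Neutrophil granule and precursor genes had a median of -0.42 (0.215), with Lcn2 called among 7.

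The other list medians in Ly6Chigh lay within the range of random lists. These were -0.09 for Ly6Chigh markers, -0.14 for Fc and complement receptors, 0.04 for chemokine receptors, where Ccr1 was called, -0.09 for cell cycle genes, -0.01 for osteoclast differentiation and 0.00 for sterol and lipid handling, where Lpl was called. Among markers of other cells they were 0.46 for NK cells, -0.15 for B cells (-0.48, percentile 1.76, among members Present on both arrays), 0.07 for plasma cells, -0.23 for T cells, 0.22 for conventional and -0.06 for plasmacytoid dendritic cells, 0.11 for red pulp macrophages and 0.04 for platelets. The median of the sex-linked genes was 0.34, and it lay above random lists after quantile normalization (percentile 98.2) and with an offset of 32 (99.0). In all 4 comparisons 0 genes of the erythroid list and 0 of the list for eosinophils, basophils and mast cells were measured.

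When both arrays were simulated without a genotype change, 100 draws gave 2 to 23 calls in Ly6Chigh (median 11), against 28 observed. The noise was normal, with the same spread for all genes of a signal bin of the 4 arrays. It left out shifts that both KO pools share, so the draws do not measure calls beyond noise. The count was 338 without a signal minimum, 207 higher and 131 lower, and 136 with the mean of all probe sets of a gene, 73 higher and 63 lower. The authors' deposited table called 851 genes higher and 818 lower, of which 108 and 18 by 2-fold or more, and among its calls were 25 of the 28 in the same direction.

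**Figure D1:**
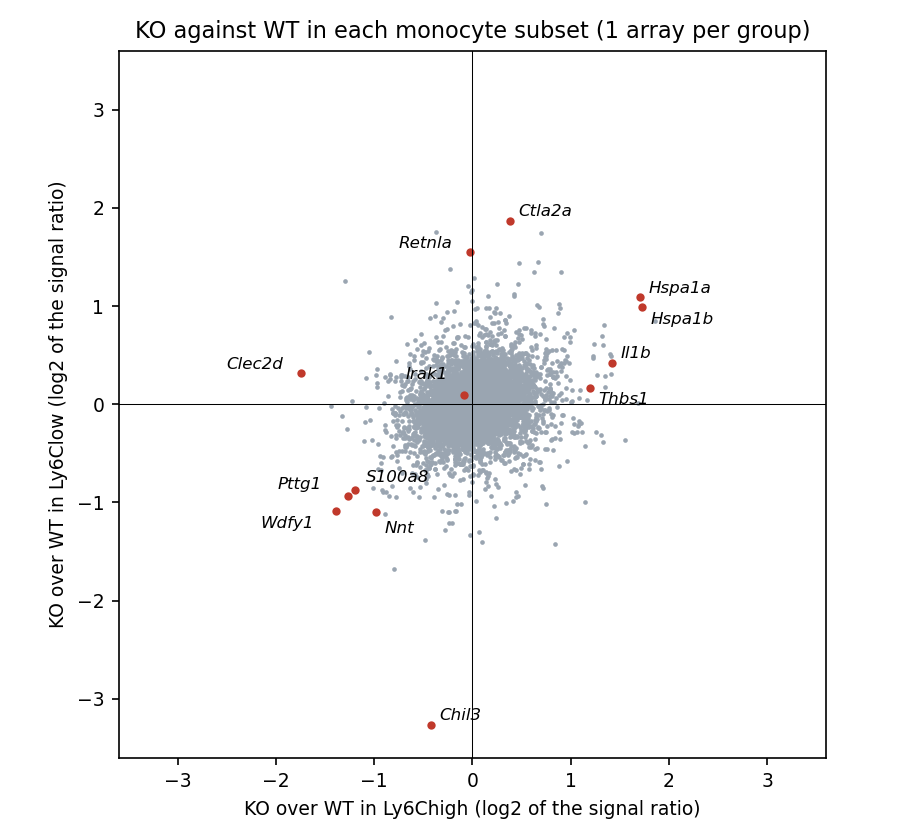
Log2 KO over WT in Ly6Chigh (x axis) against Ly6Clow (y axis) for the 8590 genes Present on all 4 arrays, 1 point per gene and 1 array per group. Hspa1a and Wdfy1 lie beyond 2-fold on both axes, Il1b and Clec2d on the x axis and Chil3 and Ctla2a on the y axis.

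In Ly6Clow monocytes, Chil3, a chitinase-like secreted protein of myeloid cells, fell by 3.26 on the log2 scale in KO, to a signal of 167.3 from 1603.7 (9.59-fold). Ctla2a, a cysteine protease inhibitor gene, rose 3.66-fold and Retnla, a secreted protein of alternatively activated macrophages, 2.93-fold. Hspa1a rose 2.13-fold and Lpp, a focal adhesion protein gene, 2.34-fold. Nnt, which encodes a mitochondrial NADPH-forming transhydrogenase, fell by 1.10 and Jade2 by 1.21.

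Of 10191 genes measured in Ly6Clow, 20 passed the rule, 13 higher and 7 lower. The chemokine gene Ccl3 rose 2.18-fold and Ppbp, a chemokine gene of platelets, 2.74-fold (signal 267.9 against 97.9). Ms4a1, which encodes CD20 of B cells, fell by 1.12, and Ly6d, listed here among plasmacytoid dendritic cell markers, by 1.25. Nnt fell under the rule with the mean of all its probe sets (-0.70), although its other Present probe set gave -1.34. With an offset of 32 Ly6d fell under the rule (-0.86), as did Hspa1a (0.999), Ccl3 (0.9997) and Ms4a1 (-0.996) by thousandths. Itgam was at log2 0.09.

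The miR-146a targets again gave 0 of 15 called, with Traf6 at 0.31, Irak1 at 0.09 and Relb at 0.26. Here too the rule called few genes (20 of 10191) and found 0 of 100 simulated changes of 0.5, so the count cannot show smaller changes. The median of the targets, 0.10, lay above random lists (percentile 99.2), but inside the range at 96.4 against lists not matched on signal. NF-kB response genes had a median of 0.26, above all random lists, with Ccl3 called among 23. Type I interferon response genes had one of 0.24 (99.99), with 0 of 22 called. Immediate early and heat shock genes had one of 0.44, above all random lists, with Hspa1a called among 15 and Hspa1b at 0.99. As in Ly6Chigh, the medians of these 3 groups lay above random lists.

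The median of osteoclast differentiation genes was 0.28 (percentile 99.98), with 0 of 12 called, and that of Toll-like receptors and adaptors 0.09 (98.5), with 0 of 17 called. With the mean of all probe sets of a gene these medians were 0.10 and 0.06 (percentile 87.3 for both). Platelet and megakaryocyte markers had a median of 0.43 (99.7), with Ppbp called among 5. B cell markers had one of -0.42 (0.75), with Ms4a1 called among 6, and plasma cell markers one of -0.49 (0.61), with 0 of 5 called. The B cell percentile was 3.12 with the mean of all probe sets, and the plasma cell median was -0.26, within the range, among members Present on both arrays. Sterol and lipid handling genes had a median of -0.17 (0.80), with 0 of 12 called, and a median of -0.08 (9.94) with the mean of all probe sets.

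The other list medians in Ly6Clow lay within the range of random lists. They were -0.08 for Ly6Chigh markers, where Chil3 was called, -0.08 for Ly6Clow markers, -0.08 for MHC class II presentation, 0.10 for Fc and complement receptors (percentile 98.2 after quantile normalization and 98.1 with an offset of 32), 0.05 for chemokine receptors, -0.04 for cell cycle genes, -0.07 for neutrophil markers (-0.40, percentile 0.24, among members Present on both arrays), -0.08 for conventional and -0.19 for plasmacytoid dendritic cells (-0.72, percentile 0.03, with the mean of all probe sets), 0.12 for red pulp macrophages and -0.06 for sex-linked genes. Of the NK, T cell and neutrophil granule lists 1, 2 and 2 genes were measured, which gives no median. Chil3, also on the neutrophil granule list, was the 1 called among them.

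For Ly6Clow, the 100 draws without a genotype change gave 1 to 14 calls (median 7), against 20 observed. These draws have the same limits as those for Ly6Chigh. The count was 322 without a signal minimum, 155 higher and 167 lower, and 126 with the mean of all probe sets, 65 higher and 61 lower. The authors' deposited table called 269 genes higher and 401 lower, of which 60 and 36 by 2-fold or more, and among its calls were 19 of the 20 in the same direction.

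**Figure D2:**
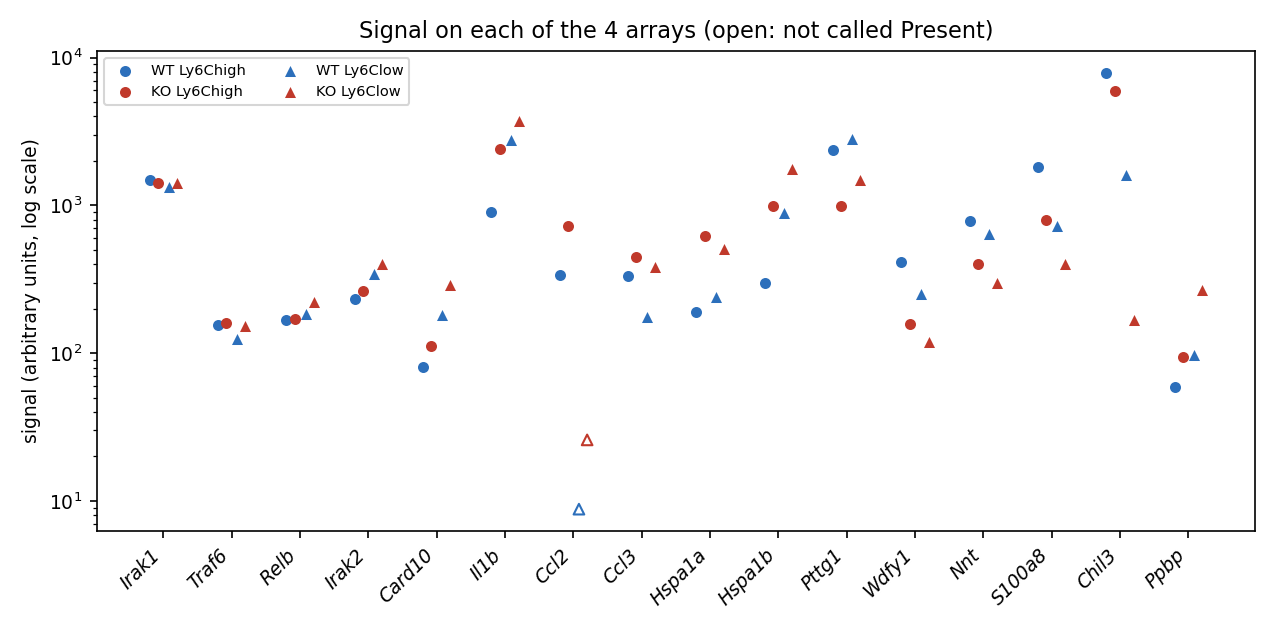
Signal (arbitrary units, log axis) of 16 genes on each of the 4 arrays, 1 symbol per array, open where the probe set was not called Present; Irak2 and Wdfy1 lie outside the rule for named genes. Chil3 reads 7929.9, 1603.7, 5932.9 and 167.3 in WT Ly6Chigh, WT Ly6Clow, KO Ly6Chigh and KO Ly6Clow, while Irak1 lies between 1337.4 and 1493.4 on all 4 arrays.

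Hspa1a, higher in KO, and Wdfy1, an endosomal adaptor of Toll-like receptor signalling, lower in KO (log2 -1.39 in Ly6Chigh and -1.09 in Ly6Clow), were the genes that passed the rule in both subsets, and 0 genes did with an offset of 32, where Hspa1a was at 0.999 and Wdfy1 at -0.92 in Ly6Clow. Wdfy1 lies outside the rule for named genes and was chosen after its values were seen. Among 9494 genes measured in both comparisons, independent lists would share 0.0185 higher and 0.0074 lower genes. Pearson's r of the KO effects across these genes was 0.146, against 0.233 among genes Present on all 4 arrays and 0.267 with an offset of 32, and genes are not independent replicates.

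Among genes that passed the rule for KO in at least 1 subset, the KO effect differed between the subsets by at least 1 on the log2 scale for 22. Of these, 10 had the higher value in Ly6Clow and 12 the lower, and these differences were not tested. Clec2d, at -1.75 in Ly6Chigh and 0.32 in Ly6Clow, differed by 2.06 and Ctla2a by 1.49, and Retnla was at -0.03 in Ly6Chigh and 1.55 in Ly6Clow. The difference was -2.84 for Chil3 (-0.42 in Ly6Chigh), -1.17 for Gcnt2, -1.13 for Jade2, -1.07 for Crybg1 and -1.03 for Thbs1. In Ly6Chigh, Jade2 had signals of 20.7 in WT (Absent) and 19.6 in KO, under the 95th percentile of Absent signals. Thbs1 in Ly6Clow, at 31.5 in WT and 35.4 in KO, lay just above it. A KO effect of these 2 genes could hardly show in those subsets. Tsc22d1, a transcriptional regulator, was at 0.00 in Ly6Chigh and 1.05 in Ly6Clow, where its other Present probe sets ranged from -1.23 to 1.55. The count was 435 without a signal minimum and 158 with the mean of all probe sets.

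The additive model of limma, which treats the subsets as the 2 arrays of each genotype, called 0 genes for genotype at an adjusted p of 0.05 among 11099, with 700 at an unadjusted p under 0.05. Coefficients were 1.40 for Hspa1a, 1.36 for Hspa1b, -1.24 for Wdfy1 (SE 0.147), -1.10 for Pttg1 (SE 0.152) and -1.04 for Nnt (SE 0.121), each with an adjusted p of 0.742. Irak1 was at 0.00, Traf6 at 0.18 (SE 0.138) and Relb at 0.14 (SE 0.136). The same limma model called 106 genes after an offset of 32, 287 with an empirical Bayes trend and 0 with quantile normalization. The trend fit set each gene's variance by its signal level alone and gave its own residual no weight. A gene whose KO effect differs between the subsets could thus be called. Chil3, for example, had an SE of 0.094 with the trend and 0.845 without it.

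Mir146 lies on chromosome 11, and the KO strain label allows sequence of another strain around it. Of the 50 measured genes on each side, Pttg1 and Jade2 passed the rule in a subset, against 44 of 10999 genes elsewhere. The median size of the log2 change was 0.223 among these neighbours and 0.208 elsewhere in Ly6Chigh, and 0.171 and 0.161 in Ly6Clow.

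More genes passed the rule between the subsets than between the genotypes. In WT, F13a1, the coagulation factor XIII A chain gene, was 171-fold lower in Ly6Clow than in Ly6Chigh, and 135-fold lower in KO. Vcan, a matrix proteoglycan gene, was at least 44.7-fold lower in WT and at least 66.5-fold lower in KO, and Ccr2, the receptor by which classical monocytes leave the marrow, fell by 2.36 and by 2.65 on the log2 scale. Fabp4, a fatty acid carrier gene, was 29.1-fold and 34.7-fold higher in Ly6Clow, the scavenger receptor gene Cd36 16.1-fold and 21.9-fold, and Itgax, which encodes CD11c, was higher by 4.14 and 3.70 on the log2 scale. Vegfc, a growth factor of lymphatic vessels, was 41.8-fold and 53.5-fold higher, and the transcription factor gene Ets1 35.5-fold and 60.6-fold.

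Of 10535 genes measured in WT, 385 were higher and 526 lower in Ly6Clow, and of 10410 in KO, 384 and 530. Among 9846 genes measured in both, 288 were higher and 415 lower in both genotypes, where independent lists would share 14.9 and 28.2, and 1 gene went opposite ways. Further genes higher in Ly6Clow in both genotypes were Dusp16 (log2 5.14 in WT, 4.54 in KO), Slc12a2 (4.89, 4.13), Cd9 (4.59, 4.79), Tgfbr3 (4.65 in WT, at least 23.1-fold in KO) and G0s2, an inhibitor of lipolysis (4.23, 4.95). Jade2, Ccnd2 and Dnah12 in WT (at least 36.2-fold, at least 25.6-fold and 17.9-fold), and Ikzf3 and Ltb in KO (4.56 and 4.46), were also among the largest. Genes lower in both were Atrnl1 (-6.74, -6.35), Cd177 (at least 47.6-fold and 39.0-fold), Met (at least 18.8-fold in WT, -5.10 in KO), Thbs1 (-4.23, -5.25), Ccr1 (-4.06, -5.03) and Cd93 (-4.21, -4.72). Capg (-4.54), Slfn5 (-4.20) and Olfm1 (at least 17.4-fold) were among the largest in WT, and Chil3 (-5.15), Ccl2 (at least 24.2-fold) and Ms4a8a (-4.33) in KO. Another Present probe set of Capg gave 0.09 in WT and another of Ets1 gave -0.06 in KO.

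Type I interferon response genes were lower in Ly6Clow, 18 of 23 in each genotype, with medians of -1.35 in WT and -1.37 in KO, below all random lists. Usp18, which dampens interferon receptor signalling, was at -3.00 and -2.85, Cxcl10 at -2.73 and -3.56, and Ifit2 at -2.52 and -2.54. Ifit3 was at -2.83 in WT and Oasl2 at -2.49 in KO. Of 11 Ly6Chigh markers, 9 were lower in each genotype, with medians of -2.31 and -2.65, among them Fn1 at -3.91 in WT and Mmp8 (at least 51.2-fold in WT, 74.9-fold in KO). Of 17 Ly6Clow markers, 13 were higher in WT and 14 in KO, with medians of 2.24 and 2.57, among them Pparg, a regulator of lipid metabolism, at 3.91 and 4.03. The Ly6c genes used for the sort were not analysed here, and Itgam was at -0.38 and -0.53.

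MHC class II presentation genes had medians of -0.56 (percentile 0.99) and -0.97 (0.01). The genes H2-DMa (-2.04, -1.96) and H2-Ab1 (-1.35, -1.80), of peptide loading and presentation, were lower and H2-Ob (2.04, 1.82) higher in both genotypes, and Ciita, the class II transactivator gene, was at -2.84 in KO. Cell cycle genes had medians of 0.69 and 0.52, with 3 of 19 higher in WT and 4 of 17 in KO. These were genes of the replicative helicase, Mcm6 (1.84, 1.90), Mcm7 (2.82-fold and 3.57-fold) and Mcm5 (1.11, 1.68), and in KO Mcm3 (1.24). Of the list, 13 of 19 members in WT and 15 of 17 in KO lay above 0, and 0 were called lower. Other members went the opposite way without a call. In the additive model, which averages the genotypes, Mki67 was at -1.54, Plk1 at -1.29 and Aurkb at -3.92. With the mean of all probe sets, Mcm6 and Mcm5 in WT (0.98 and 0.94) and Mcm5 and Mcm3 in KO (0.89 and 0.76) fell under the rule. Sterol and lipid handling genes had medians of 0.77 and 0.41, with Cd36 and Scd1 (2.92 in WT) higher and Lpl (-2.00, -1.35) lower. Abca1, a cholesterol exporter gene, was at 1.25 in KO, and at 0.44 with the mean of its probe sets. The KO median of that list was 0.15 (percentile 82.5) among members Present on both arrays.

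Fc and complement genes had medians of -0.39 (percentile 1.88; 3.62 among members Present on both arrays) and -0.21 (7.75), with the Fc receptor gene Fcgr4 higher (2.78, 3.55) and Fcgr1 lower (-1.77, -1.98). Cfb was at least 4.72-fold lower in WT and at -2.43 in KO, Cfp was at -2.30 in WT, where another Present probe set gave 0.17, and C5ar1 at 1.65 in KO, but at 0.93 with the mean of its probe sets. Toll-like receptor genes had medians of -0.16, within the range, and -0.38 (percentile 0.485), with the lipopolysaccharide co-receptor gene Cd14 at -2.69 and -2.21 and Tlr1 at -1.17 in KO. Medians of osteoclast differentiation genes were 0.03 (49.1) and 0.39 (98.2), the second 0.14 (84.4) after quantile normalization, with Acp5 (1.84, 1.56) higher and Mitf (-1.64, -1.27) lower.

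Within the range of random lists in both genotypes were miR-146a targets (0.09, 0.02), NF-kB response genes (0.15, 0.20), chemokine receptors (0.44, -0.36) and immediate early and heat shock genes (-0.02, 0.10). Among members Present on both arrays, chemokine receptors lay below random lists in WT (-0.56, percentile 0.93) and NF-kB response genes above them in KO (0.30, 99.3), as also with the mean of all probe sets (0.27, 99.2). Their called members went both ways. Cxcr4 (1.64, 1.77) and Card10 (1.17, 1.38, and 0.92 in WT with an offset of 32) were higher and Notch1 (-1.87, -1.81) lower among the targets, where Traf6 was at -0.32 and -0.07, Irak1 at -0.16 and 0.01 and Relb at 0.15 and 0.39. Cd83, an activation marker (4.40, 4.54), and Traf1 (2.28, 2.23) were higher and Ptgs2 (-4.62, -4.18) lower among NF-kB response genes, with Tnf at 2.04 in WT and Cxcl2 at -1.73 in KO. The Ly6Clow signals of Ptgs2, 6.9 in WT and 17.5 in KO, were Present but under the 95th percentile of Absent signals. Fosb (-2.65, -2.34) and Atf3 (-1.07, -1.12) were lower, and in WT Hspa1b (1.57) and Hsph1 (1.24) higher.

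Markers of other cells also differed between the subsets. Conventional dendritic cell markers were lower in Ly6Clow, 4 of 6 in each genotype, with medians of -2.34 and -2.55, among them Clec10a (-3.41, -3.71), Batf3 (-2.29, -2.62), Flt3 (at least 6.89-fold and 4.03-fold) and Cd209a (at least 5.27-fold and 7.97-fold). These dendritic cell genes moved with MHC class II. Neutrophil markers had medians of -0.91 (percentile 0.19, but -0.22 and 20.9 among members Present on both arrays) and -0.67 (0.75), with S100a8 at -1.32 in WT, and neutrophil granule genes had medians of -3.49 and -3.53, with Lcn2 at -4.68 and -3.42 and Prtn3 at least 7.12-fold and 5.07-fold lower. B cell markers had medians of 1.52 and 0.88 (98.9), with Ms4a1 at 2.45 and 2.23. Platelet markers had medians of 0.39 (88.5) and 0.82 (99.6), with Ppbp at 1.52 in KO. Medians within the range were -0.39 and -0.84 for NK cells, with Klrk1 at least 5.0-fold lower in KO, 0.14 and -0.95 for plasma cells, with Irf4 at -1.03 (-0.89 with an offset of 32) and -1.68, 0.51 for T cells in KO, with 2 genes measured in WT, and -0.46 and -0.54 for plasmacytoid dendritic cells, with Ly6d at 2.56 in WT. The plasmacytoid median turned to 0.87 in WT (percentile 98.3) with the mean of all probe sets, and in KO the plasma cell percentile was 1.70 with an offset of 32 and 1.9 among members Present on both arrays, and the NK cell percentile 2.01 against unmatched lists. They were -0.08 and -0.45 for red pulp macrophages, where Spic (1.60, 1.52) was higher, Axl lower (at least 7.88-fold and 5.68-fold) and Mrc1 at -3.40 in KO, and 0.37 and 0.01 for sex-linked genes.

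The limma model called 786 genes for subset, 326 higher and 460 lower in Ly6Clow, but 0 when all genes were tested (3086 at an unadjusted p under 0.05) and 0 with the mean of all probe sets (3085). The authors' deposited table called 892 of the 911 WT genes and 892 of the 914 KO genes changed the same way.

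**Figure D3:**
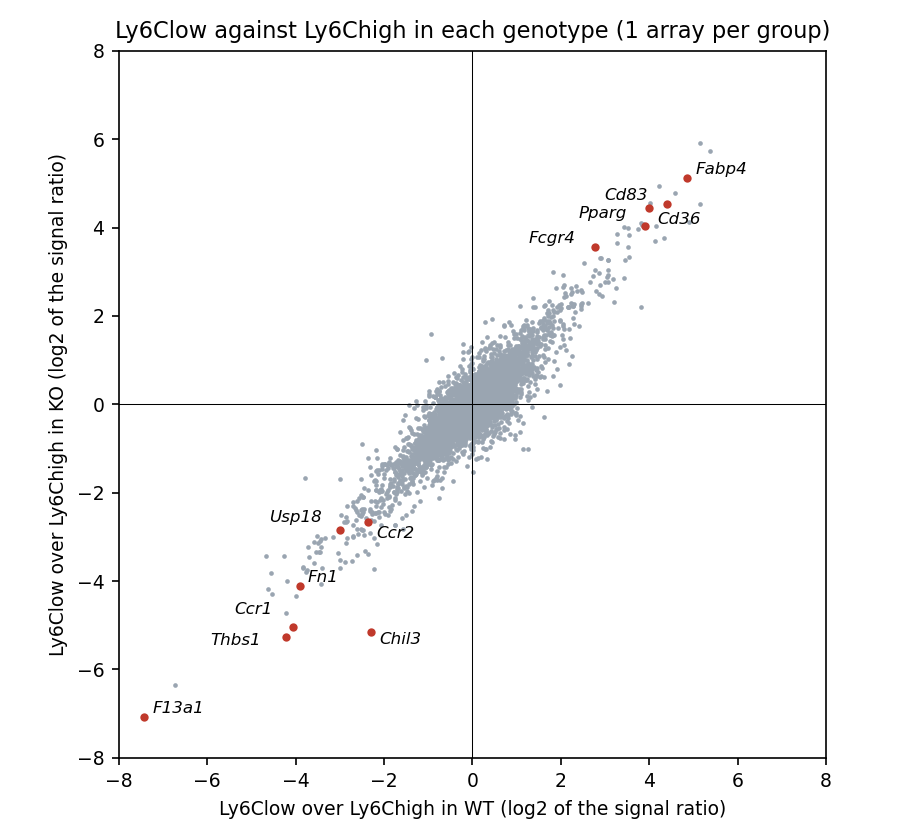
Log2 Ly6Clow over Ly6Chigh in WT (x axis) against KO (y axis) for the 8590 genes Present on all 4 arrays, 1 point per gene. Pearson's r across these genes is 0.893, and F13a1 lies at -7.42 and -7.08.

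**Figure D4:**
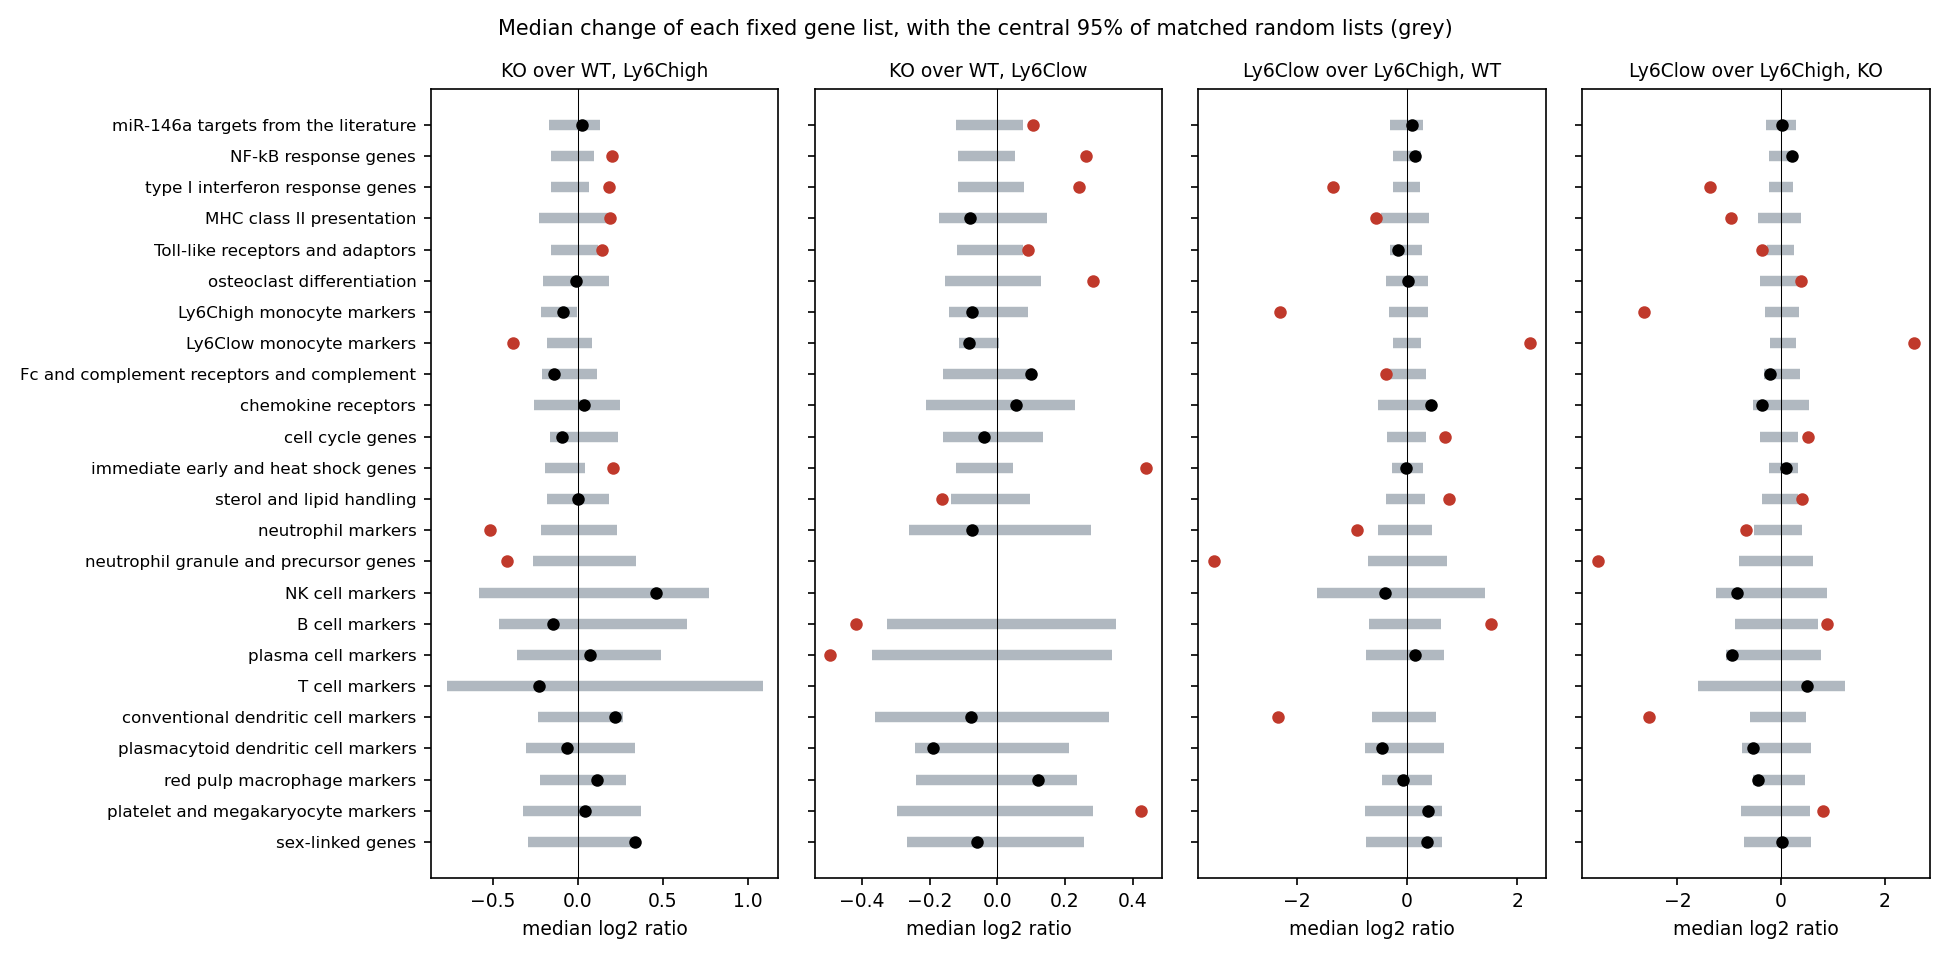
Median log2 ratio of each gene list in the 4 comparisons, 1 panel each with its own x range; grey bars span the central 95% of 10000 random lists and red marks medians outside it. Outside lay 8 lists for KO in Ly6Chigh, 10 for KO in Ly6Clow, 11 for the subsets in WT and 13 in KO.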

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

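The tests of neighbouring genes, of opposite shifts, of other probe sets for all 55 genes, of other cell types' markers and of Chil3 with its 4 comparison genes were chosen only after the result was seen, as were the genes named in this part outside the rule, and those of other probe sets for the neighbours of Mir146 and of the separate platelet list before.

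Clec2d stood out because its KO effect had opposite signs in the subsets, -1.75 in Ly6Chigh and 0.32 in Ly6Clow, a difference that was not tested. Among 10092 probe sets, control probe sets left out, that name no single gene and enter no comparison above, 23 passed the 2-fold rule for KO in Ly6Chigh, 16 for KO in Ly6Clow, 249 for the subsets in WT and 284 in KO.

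At 1.5-fold, 55 genes Present on all 4 arrays shifted the same way on both KO arrays and 11 went opposite ways, so 83.3% went the same way (exact binomial 95% interval 72.1% to 91.4%), which argues against measurement noise independent between arrays and between genes as the whole account; the interval takes genes as independent, so variation that genes share between pools stays open. Of these, Mat2b, Pttg1 and Havcr2 are 3 of the 100 measured neighbours of Mir146, a number reached by 2.88% of 9089 overlapping windows of 100 genes (median 0, highest 5). Passenger sequence around the targeted locus may thus contribute there. Neighbouring windows share most of their genes, so the share rests on far fewer separate stretches than windows. A strain variant under the probes of 1 probe set cannot be told apart for these neighbours, whose other Present probe sets, 2 of Pttg1, had a median shift of 0.162, nor for the 37 of the 55 genes without another Present probe set. For the 18 genes with one, Pttg1 included, the other probe sets had a median shift of 0.492 in the same direction (bootstrap 95% interval 0.295 to 0.809, 3 genes below 0), short of 1.5-fold but more than such a variant as the whole account allows. Strain label and the loss of miR-146a stay open for all 55 genes, as does the lysis buffer if it differed by genotype, because the design changes them together.

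The median of platelet markers on the KO Ly6Clow array lay above random lists, with 1 of 5 called. A separate list of 14 platelet genes, 8 of them measured and 0 called, had a median of 0.611 there (percentile 99.8 of lists matched on signal). Of the separate list, 4 genes were Present on the WT Ly6Clow array and 7 on the KO array, most of them dim, and 0 belong to another list. Gp1bb, Alox12, Gata1 and Mylk (log2 1.03, 0.59, 1.15 and 2.53) counted as measured only through the KO array, and Rab27b (-0.09) only through the WT array. Those Present on both, Clec1b (0.63), Vwf (0.38) and F2rl2 (-0.44), went both ways. RNA from platelets is thus a candidate source, which the separate list cannot decide. Listed platelet genes of higher signal moved unequally, Ppbp to 267.9 from 97.9, Pf4 to 283.6 from 220.2, Vwf to 265.2 from 203.9 and Itgb3 to 100.9 from 75.1. Itga2b went to 93.9 from 106.2. Gng11 (254.4 from 96.6), Pecam1 (244.7 from 88.3) and Clu (172.4 from 51.5), in neither platelet list, also passed the rule there. Whether their signal came from platelets was not tested. The CD11b beads and the sort would remove free platelets. A lower purity for all cell types alike was tested on 9 B, T and NK cell markers, whose median was -0.364 (bootstrap 95% interval -0.933 to 0.064), and cannot be told apart from no change in purity. A change in the monocytes themselves was not tested.

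Chil3 was lower on the KO Ly6Clow array, and Ly6Chigh cells carried into the WT Ly6Clow pool might account for it. Then F13a1, Fn1, Mmp8 and Vcan would reach a like share of their Ly6Chigh signal there, but their median share was at most 2.10% (highest 6.66%, for Fn1), with Mmp8 and Vcan, not Present there, set at the floor, against 20.2% for Chil3, which argues against it. Ccr2 and Hp reached 19.5% and 29.8%, but carried cells bring all their abundant transcripts, and F13a1, Present at 0.584%, leaves room for no such share. In KO the share was 2.82% for Chil3, and a genotype effect, a lysis buffer that differed and a difference between the pools stay open. Chil3 is also on the neutrophil granule and precursor list, and such cells in the WT Ly6Clow pool were not tested as its source.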

How the results depend on the processing

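The limma fits with a mean signal of at least 100, the crossed pairing, the 1.5-fold comparison and the counts without platelet and B cell genes were chosen only after the result was seen. No paired analysis was possible because with 1 array per group no replicate numbers pair arrays, beyond the additive model, which compares the genotypes within each subset with 1 residual degree of freedom. Leaving out an array would leave a group empty. The seed match comparison was not run, and the other deposited table held the same values. The 95th percentile of Absent signals was 24.6 to 29.9 on the arrays, which limits dim genes.

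Counts are given for KO in Ly6Chigh, KO in Ly6Clow and the difference of KO effects, against 28, 20 and 22. They were 17, 12 and 11 with an offset of 32, 338, 322 and 435 without a signal minimum, 13, 8 and 9 with a minimum of 500, 4, 3 and 3 at 3-fold, and 136, 126 and 158 with the mean of all probe sets. For the subsets in WT and KO, against 911 and 914, they were 1654 and 1576 without a signal minimum, 431 and 424 with a minimum of 500, and 423 and 432 at 3-fold. Fewer or more genes could pass by construction of these settings. The offset shrinks each log2 ratio between 2 arrays, so it could only remove calls from the pairwise counts. The mean of probe sets took in probe sets that are not Present, while signal and detection were those of the brightest one. Dim probe sets could thus add or remove calls, and how much they did was not tested. The authors' deposited change calls gave 1669, 670, 4354 and 4066 genes, and the cause was not tested. Median centring gave 29 genes in Ly6Chigh, 14 higher and 15 lower, against 17 and 11. Without the members of the platelet and B cell lists the KO counts were 28 and 18. Only list members were left out, so these counts do not show how many calls came from such cells.

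With limma, 0 genes for genotype (700 at an unadjusted p under 0.05) became 106 with the offset, 287 with an empirical Bayes trend and 273 with a mean signal of at least 100 and trend. Both trend fits set a gene's variance by its signal level alone, so genes with unlike KO effects in the subsets could be called. On simulated arrays without a genotype change the trend fit called 12 genes with variances equal among genes of the same signal level. It called 0 with variances drawn from the prior. A crossed pairing of the arrays gave 0 genes under the settings of the report, 4 with the offset and 1 among genes Present on all 4 arrays. It gave 5 with trend and 2 with a mean signal of at least 100 and trend. That fit takes a KO shift common to both subsets for noise, so its counts do not show how many genotype calls noise would give. For subset, 786 genes became 4317 with the offset, 3352 among genes Present on all 4 arrays, 4590 with trend, 0 with all genes and 0 with the mean of all probe sets. The cause was not tested.

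The number of genes called in both subsets for KO, 2, was 0 with the offset, and 55 at 1.5-fold among genes Present on all 4 arrays. With 25 genes on each side of Mir146, 1 was called in place of 2. Of the list medians under the alternatives, 510 kept their place inside or outside the range of random lists, 14 moved out of it and 20 into it. Of the named genes' values, 712 kept their side of the rule and 20 fell under it, and none changed sign where called.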

Other observations

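The test of neutrophil markers was chosen only after the result was seen, as were the genes named in this part outside the rule.

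Several genes stood lower or higher on both KO arrays without passing the 2-fold rule on both. Bcl2, an inhibitor of apoptosis, was at -0.88 in Ly6Chigh and -0.90 in Ly6Clow, Havcr2, an inhibitory receptor gene, at -0.92 and -0.87, and Ddit4 and Fkbp5, which glucocorticoids induce, at -0.97 and -0.66 and at -0.93 and -0.60. Ide, the insulin-degrading enzyme gene, was at 0.73 and 0.80, Erdr1 at 0.88 and 0.93 and Nfil3 at 0.64 and 0.70. Nnt was at -0.98 and -1.10. C57BL/6J mice carry a deletion in Nnt, the labels do not give the WT substrain, and substrain was not tested.

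Fosb was at 0.68 and 0.99, Atf3 at 0.64 and 0.60, Ier3 at 0.96 and 0.73 and Ptgs2 at 0.90 and 1.34, although Ptgs2 had signals of 17.5 and 6.9 in Ly6Clow. The immediate early gene Egr1 was at -0.47 and -0.55. Ms4a1 was at -0.89 and -1.12, Spib at -0.81 and -0.84 and Pou2af1 at -0.80 and -1.68.

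S100a8 was at -1.19 and -0.87 and S100a9 at -0.85 and -0.93. The other measured neutrophil markers had a median of -0.106 in Ly6Chigh (6 genes, bootstrap 95% interval -0.915 to 0.231) and 0.177 in Ly6Clow (4 genes, -0.216 to 0.413). Neutrophil granule and precursor genes had a median of -0.42 in Ly6Chigh (7 genes, percentile 0.215), with Lcn2 at -1.23. In Ly6Clow 2 of them were measured, and Chil3, which is also on this list, was the 1 called (-3.26).

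The Y-linked gene Eif2s3y had signals of 1150.9 to 1274.3 on the 4 arrays and Xist, expressed from the inactive X chromosome, 16.6 to 22.0.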
